A study of Rattus norvegicus with 8 samples.

How the data were processed

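The series held 8 one-colour arrays of RNA from sorted CD9-positive testis cells, 4 from young rats (4 months) and 4 from aged rats (21 months), grouped by the age in the labels. Per the labels' protocols, total RNA was extracted on silica columns and 18 ng per sample was amplified linearly with the Cy3 dye. Per the file headers, the deposited scanner output came from Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes give version 12.5 of that software, and the probes were designed on the rat build rn4. No coordinates were used. Each array held 62976 spots, of which 58717 were not controls and represented 30367 probes.

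The deposited processed signal is an intensity on a linear scale from which, per the file headers, the software had subtracted background and a spatial trend, with no scaling between arrays. The deposited median spot and local background signals are raw intensity values, and other deposited columns mark each spot as well above background, saturated or an outlier with 0 or 1. A series table of the authors holds log2 values of the same arrays for 30505 probes, all matching a probe of the scanner output. Each probe of that table had a median of 0 over the 8 arrays (within 5e-07), and its differences between arrays followed those of the scanner signals over 9169 bright probes with slopes of 0.936 to 1.005 and r of at least 0.967 across probes. Its column medians were 0.09, −0.07, −0.14 and −0.06 for young replicates 1 to 4 and −0.02, 0.05, 0.07 and −0.003 for aged replicates 1 to 4. The scale and direction of the table were settled by this comparison, and how arrays were scaled before the centring stayed unknown.

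Control spots and outlier spots were left out, log2 processed signals were taken, and the 75th percentile over non-control probes of each array was subtracted. Spots of a probe were averaged. Probes were named by matching their accession, without version, to the RefSeq gene table of assembly GRCr8, which was used for names only. Of the probes, 17998 matched 15154 genes and 12369 stayed unnamed and were not tested in the main analysis. A probe was kept if at least 0.5 of its spots were well above background on every array of at least 1 group and each group had at least 2 values, which left 11950 probes. For the 1564 tested genes with several probes the probe with the highest mean was used. Among the 67 called genes, 14 had several probes, and in 1 of these the probes differed in direction. Of the 10236 genes tested, 2 were not well above background on any young array and 9 on any aged array, and no spot was saturated. For a gene below background on all arrays of a group, the fold was taken against the higher, per array, of its own value and the lowest value of any probe well above background.

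Differences between aged and young arrays were tested with limma 3.58.1 (lmFit and eBayes, two-sided, 9.15 moderated degrees of freedom) in R 4.3.3, with data.table (1.17.8) and jsonlite (2.0.0). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values given for genes come from this limma fit. The 32 gene lists, markers of cell types that a testis sort could hold and groups of genes for repair, metabolism, stress, immunity, matrix, signalling and germ cell programmes, were tested with limma's camera with a preset correlation of 0.01 where at least 5 members were measured. Adjustment was over the 32 lists. Beside it stood camera with an estimated correlation, fry, which tests whether the members of a list move one way without comparing them with other genes, and an exact two-sided permutation test of the list mean per array, whose smallest p with 4 against 4 arrays is 0.0286. Gfra1, Ret, Dusp6, Kit, Csf1r and Cxcr4 stand both in the signalling list and in another list, and no other gene is shared. The median and the member counts refer to the log2 change, aged minus young.

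The lists, the rule for naming genes, the test and most alternatives were chosen before the data were examined. The rule named the 12 largest rises and the 12 largest falls among called genes with separated groups, up to 4 called members of each list described or up to 2 members with the smallest p, and Cd9, Zbtb16, Gfra1, Ret, Id4, Ddx4 and Kit in every case. Members of lists that were not called are named only where they were called themselves, which gave 60 genes. Genes named outside this rule are said to have been chosen after their values were seen.

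The alternatives covered quantile, median and no scaling, normexp background correction with an offset of 50, the authors' log2 values, the filter on dim probes, outlier spots, the mean of a gene's probes, the variance model, array weights, the replicate number as a block, other thresholds, other list tests, and leaving out each array in turn. The scanner output holds no mean spot signal, so normexp was run on the median spot signal and the median background. Scaling to spike-in RNA (4 probes with a signal above 100 on all arrays), the mean of the spermatid markers as a covariate, leaving out young replicate 1 and aged replicate 2 together, and testing unnamed probes too were added after the data were seen. Spike-in RNA lay 1.38 ± 0.30 above the 75th percentile on young arrays and 1.83 ± 0.18 on aged arrays (log2, SD, n = 4), a difference of 0.45 (exact permutation p = 0.0857). Young replicate 1 was at 1.79, inside the aged range (1.64 to 2.06), and the other young arrays were at 1.07 to 1.35. The software's own spike-in fit gave slopes of 1.06 to 1.09 on young replicate 1 and aged replicates 2 to 4, and a slope of 0 with a detection limit of −1 on the other 4 arrays. Values scaled to spike-in RNA rest on these levels. For a gene measured on all arrays this scaling lowers the log2 change by the same 0.45. Gene values and list medians that turn with it share that shift.

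The test was checked on simulated data with the spread of these arrays, 10234 genes and 200 changed genes for the aged and young groups. It recovered 10.4% of changes of 0.5 on the log2 scale, 77.6% of changes of 1 and 98.5% of changes of 2, with 9 unchanged genes among 133 calls. With no change simulated, 0 genes and 0 lists were called, and raising the spermatocyte list by 0.5 gave 1 called list. The simulated genes were drawn independently of each other, while the estimated correlation within the spermatid list was 0.93. The simulation therefore could not check the list test on correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.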

Results

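Cells positive for CD9 were sorted by flow cytometry from testes of Sprague Dawley rats whose germ cells carry a green fluorescent protein transgene. Their RNA was hybridised to one-colour Agilent rat expression arrays. CD9 is a cell-surface tetraspanin present on spermatogonia, the germ cells that include the stem cells of the testis, and on other cell types as well. The 8 arrays formed 2 groups of 4, from rats of 4 months (young) and of 21 months (aged), each labelled from 18 ng of RNA. The comparison addressed which transcripts differed in abundance between aged and young sorted cells. The 75th percentile of the processed signal, to which each array was scaled, ranged from 395 to 641 intensity units, and 63.0% to 72.0% of the 30367 probes were well above background on an array. After filtering, 10236 named genes were tested, and the number of arrays limits the precision of the values. The labels do not state whether the arrays came from separate animals, so the p-values measure the spread between these samples, which may be technical.

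Several genes that act in meiotic recombination and chromosome pairing were among those higher in aged than in young cells. Spata22 and Meiob, whose proteins bind single-stranded DNA together during recombination, rose by 1.43 ± 0.23 and 1.19 ± 0.17 on the log2 scale (SE, n = 4 per group, adjusted p = 0.0465 for both). Sycp3, a structural component of the chromosome axis in meiosis, rose by 1.19 ± 0.20, and Msh4 and Msh5, which stabilise crossover intermediates, rose by 1.11 ± 0.18 and 1.19 ± 0.16 (adjusted p = 0.0465 for each). Mcmdc2, an MCM-domain gene of meiotic recombination, rose by 1.36 ± 0.16 (adjusted p = 0.0354), and Spdya, an activator of cyclin-dependent kinase, rose by 1.01 ± 0.16 (adjusted p = 0.0465). Outside meiosis, Tg, which encodes the precursor of thyroid hormones, had the smallest adjusted p of all genes tested (0.0314) with a rise of 1.31 ± 0.13.

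Pparg, the nuclear receptor of adipocyte differentiation, rose by 0.99 ± 0.15, Apom, an apolipoprotein, by 0.996 ± 0.163, and Adh4, an alcohol dehydrogenase that was above background on 1 of 4 young arrays, by 1.001 ± 0.169 (adjusted p = 0.0465 for each). Atraid rose by 0.86 ± 0.10 (adjusted p = 0.0354). The largest fall was in Akap14, a kinase-anchoring protein of sperm flagella and cilia, which fell by 2.80 ± 0.44 and was above background on 2 of 4 aged arrays. The ammonium transporter Rhcg fell by 2.28 ± 0.39 (2 of 4 aged arrays above background), the disintegrin gene Adam34 by 1.97 ± 0.33 (3 of 4) and the proton-sensing receptor Gpr4 by 1.97 ± 0.34 (1 of 4). Cspg4, a proteoglycan of pericytes, fell by 1.55 ± 0.27, the Ras-related Mras by 1.43 ± 0.23, and the mitochondrial ferritin Ftmt by 1.27 ± 0.21. The adhesion receptor Adgrl2 (3 of 4 aged arrays above background) fell by 1.10 ± 0.17 and the actin crosslinker Actn1 by 1.08 ± 0.18. The sulfatase Arsi fell by 1.03 ± 0.14, and each of these falls had an adjusted p of 0.0465. The zinc transporter Slc39a12 fell by 0.94 ± 0.17 (3 of 4 aged arrays above background, adjusted p = 0.0484). The protease gene Bace2 was not well above background on any aged array. It was 2.12-fold lower there in the processed signal, which is the measured fold and not a lower limit (adjusted p = 0.0465). The sizes of these falls and of the rise in Adh4 depended on the background correction. With normexp correction, which adds an offset of 50, and quantile or percentile scaling, Akap14 changed by −0.74 or −0.76, Rhcg by −0.55 or −0.57, Cspg4 by −0.85 or −0.91, Mras by −0.49 or −0.52, Ftmt by −0.60 or −0.65, Adam34 by −0.64 or −0.67 and Gpr4 by −0.52 or −0.51. Of these Rhcg, Cspg4, Mras and Ftmt were called under both settings and the others with percentile scaling alone, as was Actn1 (−0.38 or −0.43). Under neither setting were Adgrl2 (−0.22 or −0.23), Arsi (−0.29 or −0.31), Slc39a12 (−0.19 or −0.20), Adh4 (0.30 or 0.32) and Bace2 (−0.14 for both) called.

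**Figure D1:**
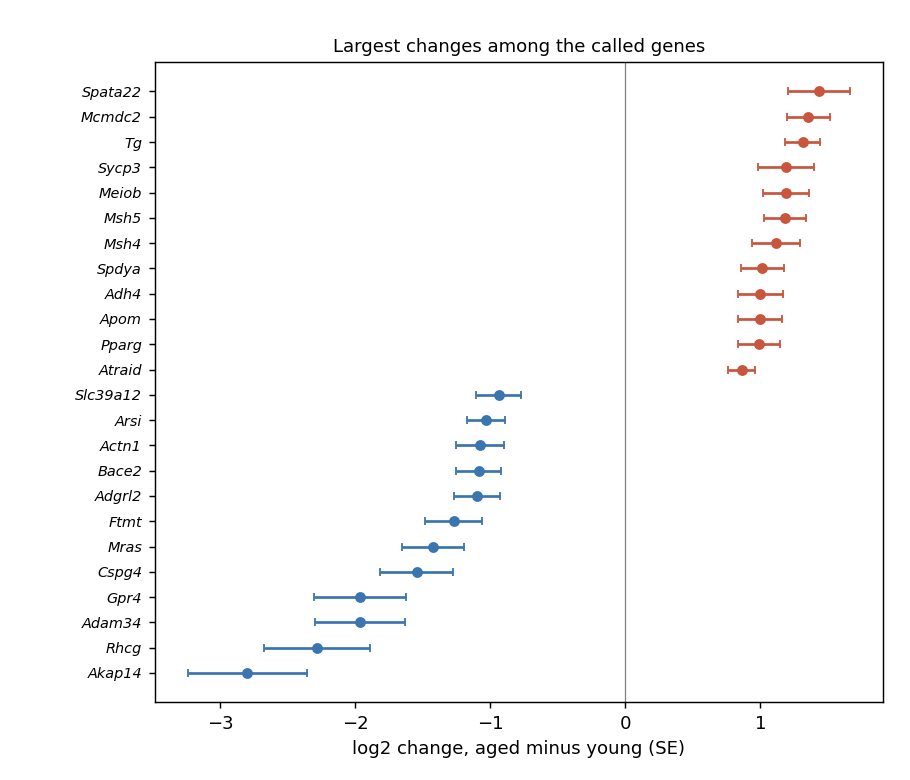
Log2 change (aged minus young, 4 arrays per group) of the 12 genes with the largest rise and the 12 with the largest fall among the genes with an adjusted p under 0.05; points are estimates and bars are standard errors. The rises reach 1.43 (Spata22) and the falls −2.80 (Akap14, above background on 2 of 4 aged arrays).

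In total 67 of the 10236 genes changed in the limma test (Benjamini-Hochberg adjusted p from 0.0314 to 0.0484), of which 51 rose and 16 fell, by 0.56 to 2.80 in size on the log2 scale. In each of these 67 genes the 4 aged values lay on one side of the 4 young values, as they did in 1464 of all genes tested (14.3%). For genes measured on all arrays, the mean share over the 35 splits into 4 and 4 is 2.857% by construction. Genes that move together can put 1 split far above that mean. The share was not counted for the other splits, so 14.3% alone does not show an effect of age. The median gene was 0.11 higher in aged cells on the log2 scale, so list medians near 0.11 mark no departure from the other genes. Scaling to array medians moved this value to 0.26, and scaling to spike-in RNA, chosen after the data were seen, moved it to −0.35. The share of rises among the calls was 76.1%. It was 57.6% (363 of 630) with normexp background correction before the percentile scaling and 86.6% (219 of 253) with normexp and quantile scaling. With scaling to spike-in RNA it was 0.567% (6 of 1059). Without young replicate 1, 3776 genes changed (2282 higher, 1494 lower), all 67 among them in the same direction, which separated groups fix beforehand. Leaving out any other single array left at most 1 gene, with 1951 to 3009 genes at an unadjusted p under 0.05. No gene was called in limma with no scaling (1389 at an unadjusted p under 0.05), with no filter on dim probes (3339), with the replicate number as a block (3231) or with unnamed probes tested too (4929). All arrays shared 1 slide and 1 scan, with the young arrays in one row of the slide and the aged arrays in the other, so slide position and age cannot be told apart.

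Markers of spermatocytes, the germ cells in meiosis, were higher in aged cells as a group, with a median log2 change of 0.65 over 24 genes (limma camera, adjusted p = 6.60e-05, and adjusted p = 0.597 with an estimated correlation). Of the 24 members, 7 rose and 17 did not pass over all genes tested, while 18 passed as higher and 4 as lower when adjusted over the list alone. Without young replicate 1, 16 passed as higher and 4 as lower over all genes. The rises comprised Spata22, Meiob, Sycp3, Msh4, Msh5, the synaptonemal complex gene Syce1 (0.72 ± 0.11, adjusted p = 0.0465) and the meiotic recombinase Dmc1 (0.84 ± 0.15, adjusted p = 0.0465), the last chosen after its values were seen. The 5 members with lower values, also named after their values were seen, were Ccna1 (−1.54, adjusted p = 0.0527), Pgk2 (−1.02, adjusted p = 0.140), Ldhc (−0.94, adjusted p = 0.149), Clgn (−0.50, adjusted p = 0.151) and Hspa2 (−0.39, adjusted p = 0.273). Ccna1 is a cyclin of the meiotic divisions, Pgk2 and Ldhc are germ-cell forms of glycolytic enzymes, and Clgn and Hspa2 are chaperones. The mean of the list lay between −0.26 and −0.19 on all young arrays, replicate 1 included, and between 0.07 and 0.44 on the aged arrays (log2, each gene centred on its mean over the 8 arrays). The self-contained fry test of limma also passed for this list (adjusted p = 0.00824). Its exact permutation p of 0.0286 was the smallest that 4 against 4 arrays can give. The median stayed above 0 under all scalings tried, down to 0.19 with spike-in RNA.

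**Figure D2:**
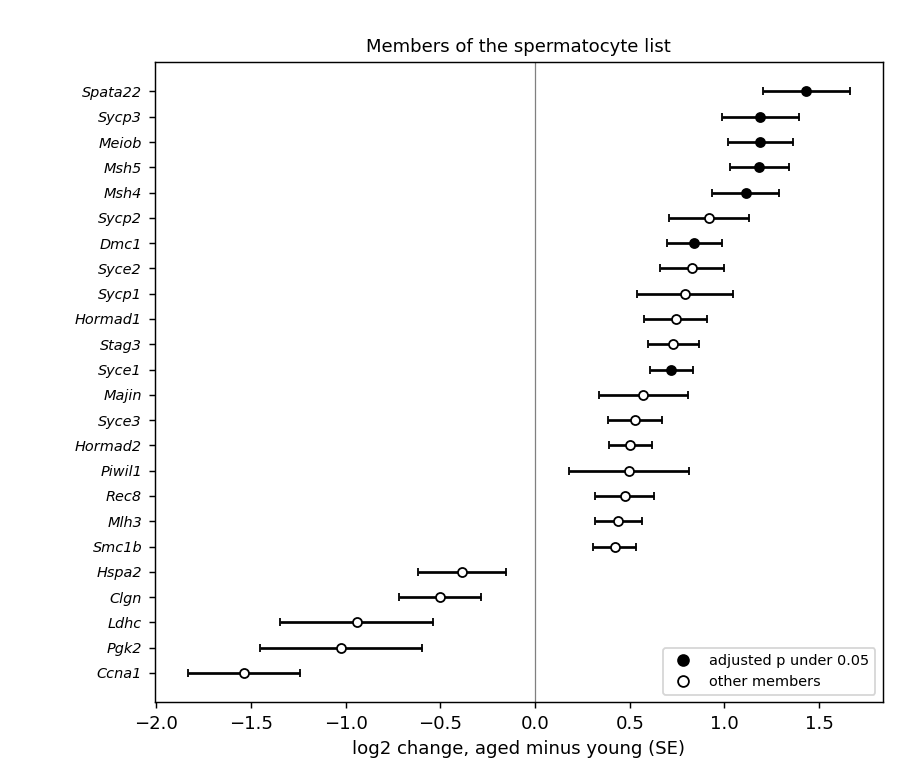
Log2 change (aged minus young, 4 arrays per group) of the 24 tested members of the spermatocyte list; points are estimates, bars are standard errors, and filled points mark an adjusted p under 0.05. The 7 filled members lie between 0.72 (Syce1) and 1.43 (Spata22), and 5 members lie below 0, down to −1.54 (Ccna1).

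Of the 4 lists of DNA repair genes 3 were called higher to a smaller extent, and base excision repair was not called (median 0.15, adjusted p = 0.459). Double-strand break repair had a median of 0.26 over 26 genes, 25 of them higher (adjusted p = 0.00379, and adjusted p = 0.624 with an estimated correlation). Over all genes tested 1 member rose, against 2 adjusted over the list alone. That member was Brca2, which loads recombinases onto DNA breaks (0.81 ± 0.14, adjusted p = 0.0484). Mismatch repair had a median of 0.27 over 15 genes, 13 higher (adjusted p = 0.0244, and adjusted p = 0.624 with an estimated correlation). Its leading members were the clamp loader subunits Rfc4 (0.40, adjusted p = 0.0680) and Rfc3 (0.37, adjusted p = 0.0906), and 0 members passed over all genes or adjusted over the list alone. Nucleotide excision repair had a median of 0.25 over 17 genes, 13 higher (adjusted p = 0.0342, and adjusted p = 0.631 with an estimated correlation). The transcription factor subunits Gtf2h2 (0.49, adjusted p = 0.0561) and Gtf2h5 (0.35, adjusted p = 0.0906) led it, with 0 members passing over all genes and 1 adjusted over the list alone. The mismatch and nucleotide excision lists were not called with quantile scaling, with normexp and quantile scaling or with scaling to spike-in RNA, and over all 27 alternatives they were called in 19 and 18, against 24 for double-strand break repair. With scaling to spike-in RNA the medians of the 3 called lists turned to −0.19, −0.18 and −0.20, against −0.35 for the median gene. In young replicate 1 the double-strand break list mean was 0.01, against −0.30 to −0.10 on the other young arrays and 0.04 to 0.41 on the aged arrays.

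Markers of spermatids, stromal cells and macrophages were called lower in aged than in young samples by camera with the preset correlation alone. They did not pass in fry (adjusted p = 0.166, 0.139 and 0.217) or the exact permutation test of list means (p = 0.114, 0.114 and 0.229). All 29 spermatid markers had lower values, with a median log2 change of −0.95 (adjusted p = 7.42e-12, and adjusted p = 0.600 with an estimated correlation). Of these, 0 passed over all genes and 4 adjusted over the list alone. The acrosomal protease Acr (−1.10, adjusted p = 0.0531) and the flagellar Tekt2 (−1.97, adjusted p = 0.0561) had the smallest p among them. All 15 markers of peritubular myoid and stromal cells had lower values (median −1.47, adjusted p = 2.12e-08, and adjusted p = 0.600 with an estimated correlation). Over all genes 0 passed, against 14 adjusted over the list alone, and the collagens Col1a1 (−0.90, adjusted p = 0.0542) and Col3a1 (−1.87, adjusted p = 0.0561) led the list. All 16 macrophage and myeloid markers had lower values (median −0.67, adjusted p = 2.74e-05, and adjusted p = 0.600 with an estimated correlation). Here 0 passed over all genes and 2 adjusted over the list alone, and the median was −0.42 without young replicate 2 and −0.36 without aged replicate 2. Adgre1, the macrophage surface marker F4/80, changed by −1.97 (adjusted p = 0.0561) and the leukocyte actin regulator Coro1a by −0.50 (adjusted p = 0.0565). In the basement membrane and matrix list 13 of 14 genes had lower values (median −0.41, adjusted p = 2.74e-05, and adjusted p = 0.597 with an estimated correlation). The laminin Lamc1 (−0.62, adjusted p = 0.0640) and the collagen Col4a1 (−1.76, adjusted p = 0.0782) led it, and 0 members passed over all genes against 5 adjusted over the list alone. The matrix list median was −0.27 without aged replicate 2, and its fry adjusted p was 0.0744. With normexp correction and quantile or percentile scaling Adgre1 changed by −0.52 or −0.54, Col3a1 by −0.58 or −0.60 and Acr by −0.58 or −0.63. With quantile scaling after normexp Col4a1 changed by −0.93 (−1.001 with percentile scaling), Coro1a by −0.33 and Lamc1 by −0.36.

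The sperm chromatin genes Tnp1 and Prm1, named after their values were seen, gave signals far above the 75th percentile of every array although the cells had been sorted for CD9. Their log2 signals above that percentile were 7.40 ± 0.53 and 7.30 ± 0.56 (mean and standard deviation) in young cells and 6.86 ± 0.37 and 6.64 ± 0.58 in aged cells. Neither change was detected (adjusted p = 0.208 and 0.207). The means of the marker lists also varied within the groups. The spermatid list mean was −0.58 in young replicate 1 and 0.57 to 1.09 on the other young arrays, against −1.19 to −0.09 on the aged arrays. The myoid and stromal list mean was −0.76 in young replicate 1, 1.08 to 1.28 on the other young arrays and −1.43 to −0.30 on the aged arrays. The macrophage list mean was −0.47, 0.49 to 0.99 and −1.29 to 0.45 in the same order. Without young replicate 1 all 29 spermatid markers and all 15 stromal markers passed as lower over all genes, with list medians of −1.30 and −2.01. Of the 16 macrophage markers 7 did so. Young replicate 1 had the lowest young mean for each of these lists, so leaving it out widened the differences beforehand. With that array kept, 0 members of these lists passed over all genes. The falls without it are therefore no separate evidence of an effect of age. With the spermatid marker mean as a covariate, an alternative chosen after the data were seen, 0 genes were called (1294 at an unadjusted p under 0.05) and 5 lists were called, 3 of the 15 among them, with the spermatocyte list kept (median 0.54). The stromal and macrophage lists were not called with this covariate, with medians of −0.23 and 0.14, nor was the spermatid list, by construction.

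**Figure D3:**
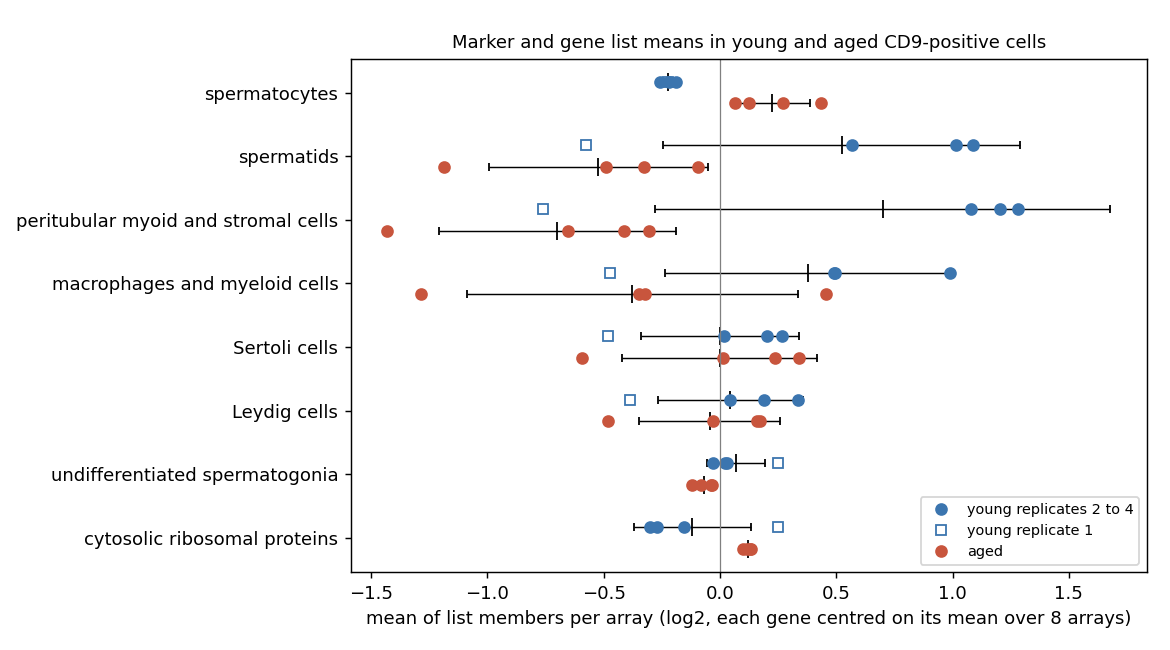
Mean of the members of 8 lists on each array (log2, each gene centred on its mean over the 8 arrays), with young arrays in blue, young replicate 1 as an open square and aged arrays in red; vertical ticks are group means and bars are standard deviations (n = 4). The spermatocyte means do not overlap between the groups (−0.26 to −0.19 against 0.07 to 0.44), while young replicate 1 lies among the aged arrays for spermatid and stromal markers (−0.58 and −0.76).

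Spermatogonial markers moved in both directions, with small list medians. Cd9, the antigen used for sorting, changed by −0.16 ± 0.16 (adjusted p = 0.492, and −0.013 without aged replicate 4), and Zbtb16, a transcription factor of undifferentiated spermatogonia, by −0.09 ± 0.18 (adjusted p = 0.739). The Zbtb16 value turned positive with quantile (0.04) and median scaling (0.06) and without young replicate 1 (0.08). Gfra1 and Ret, the receptor subunits for GDNF, changed by −0.89 ± 0.25 (adjusted p = 0.0742) and −0.41 ± 0.14 (adjusted p = 0.104). Without young replicate 1 Gfra1 passed at −1.10 (adjusted p = 0.00784, range over the alternatives 0.00283 to 0.541). Id4, a regulator of stem cell self-renewal, changed by −0.52 ± 0.32 (adjusted p = 0.280, above background on 2 of 4 aged arrays). The Id4 value was −0.039 or −0.049 with normexp correction and quantile or percentile scaling, and −0.29 without young replicate 4. The germ cell helicase Ddx4 changed by −0.21 ± 0.19 (adjusted p = 0.448) and the receptor Kit, a marker of differentiating spermatogonia, by 0.13 ± 0.15 (adjusted p = 0.571), which became −0.33 with scaling to spike-in RNA. When each array was left out in turn Ddx4 ran from −0.36 to −0.091 and Kit from 0.059 to 0.24. As a list, undifferentiated spermatogonia had a median of −0.15 with 14 of 19 genes lower (adjusted p = 0.0413, and adjusted p = 0.624 with an estimated correlation). Over all genes 0 members passed, against 1 adjusted over the list alone, the adhesion molecule Epcam at 0.46 (adjusted p = 0.0561). The GDNF, FGF and KIT signalling list had a median of −0.04 with 14 of 28 genes lower (adjusted p = 0.0291, and adjusted p = 0.600 with an estimated correlation). In it 0 members passed over all genes or adjusted over the list alone, and the receptor Fgfr2 stood at −0.39 (adjusted p = 0.0771). With median scaling, which moved the median gene from 0.11 to 0.26, the medians of these lists were 0.01 and 0.11. Both lists still tested as lower there but were not called. Leaving out each array in turn gave −0.085 to −0.0015 for the signalling list. Neither list was called without young replicate 1 (medians −0.059 and −0.0015, limma camera, adjusted p = 0.362 and 0.142), whose own list means (0.25 and 0.14) lay above those of the other 7 arrays. The differentiating spermatogonia list was not called (7 genes, median 0.13, adjusted p = 0.736), although its member Tex101, a germ cell surface glycoprotein, rose by 0.75 ± 0.11 (adjusted p = 0.0465).

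Energy metabolism and translation lists shifted by small amounts. Cytosolic ribosomal proteins had a median of 0.24 with 71 of 72 genes higher (adjusted p = 1.37e-04, and adjusted p = 0.738 with an estimated correlation). Examples were Rpl15 at 0.45 (adjusted p = 0.0569) and Rps19 at 0.43 (adjusted p = 0.0885). Oxidative phosphorylation had a median of 0.24 with 65 of 69 genes higher (adjusted p = 2.65e-04, and adjusted p = 0.738 with an estimated correlation). Its leading members were Ndufa1 of complex I at 0.64 (adjusted p = 0.0561) and Atp5pb of the ATP synthase at 0.42 (adjusted p = 0.0722). Both medians turned negative with scaling to spike-in RNA (−0.22 for each, against −0.35 for the median gene). With quantile scaling neither list was called, and the ribosomal list was tested as lower (median 0.04, adjusted p = 0.961). Young replicate 1 had the highest ribosomal list mean of all arrays (0.25), against −0.30 to −0.16 on the other young arrays and 0.10 to 0.13 on the aged arrays, and the list median without it was 0.36. Its oxidative phosphorylation list mean (0.21) was also the highest, against −0.27 to −0.18 and 0.04 to 0.18 in the same order. Glycolysis had a median of −0.21 with 19 of 23 genes lower (adjusted p = 8.90e-04, and adjusted p = 0.597 with an estimated correlation), and −0.13 without aged replicate 2. The phosphofructokinase Pfkm stood at −0.48 (adjusted p = 0.0712) and the aldolase Aldoc at −0.35 (adjusted p = 0.0890). In these 3 lists 0 members passed over all genes or adjusted over the list alone.

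Immune lists were called lower in aged samples by camera, as the macrophage markers were. The interferon response and antigen presentation list had a median of −0.27 with 19 of 26 genes lower (adjusted p = 0.00142, and adjusted p = 0.600 with an estimated correlation). Its members passing numbered 0 over all genes and 1 adjusted over the list alone. Tap1, a peptide transporter of antigen presentation that was above background on 1 of 4 aged arrays, changed by −0.72 (adjusted p = 0.0561) and the RNA sensor Ifih1 by −0.48 (adjusted p = 0.0796). Cytokines and chemokines had a median of −0.25 with 13 of 16 genes lower (adjusted p = 0.0113, and adjusted p = 0.600 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. The chemokine Ccl5 stood at −0.86 (adjusted p = 0.0828) and the macrophage growth factor Csf1 at −0.65 (adjusted p = 0.107, above background on 2 of 4 aged arrays). With normexp correction and quantile or percentile scaling the changes were much smaller, −0.11 or −0.089 for Tap1, −0.097 or −0.11 for Ifih1, −0.41 or −0.47 for Ccl5 and −0.11 or −0.12 for Csf1. The cytokine list median was −0.45 without young replicate 1 and −0.16 without aged replicate 2. The cytokine list mean was −0.42 in young replicate 1 and 0.24 to 0.50 on the other young arrays, and −0.70 to 0.09 on the aged arrays.

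The remaining lists were not called. Cell cycle genes had a median of 0.13 (30 genes, adjusted p = 0.141), and the list was called higher without young replicate 1 (adjusted p = 0.0330, and adjusted p = 0.456 with an estimated correlation). Its member Bub1, a mitotic checkpoint kinase, rose by 0.64 ± 0.11 (adjusted p = 0.0465). Somatic markers gave medians of 0.06 for Sertoli cells (15 genes, adjusted p = 0.978), 0.05 for Leydig cells (13 genes, adjusted p = 0.647) and −0.16 for endothelial cells (8 genes, adjusted p = 0.141). Those of blood cells were 0.01 for lymphocytes (9 genes, adjusted p = 0.409) and −0.12 for erythroid cells and platelets (11 genes, adjusted p = 0.409). The Sertoli member Rhox5, a homeobox gene of the X chromosome, rose by 0.82 ± 0.13 (adjusted p = 0.0465). Medians were 0.15 for base excision repair (adjusted p = 0.459), 0.14 for DNA methylation and chromatin (adjusted p = 0.558), and 0.14 for heat shock and protein folding (adjusted p = 0.558). Apoptosis had 0.15 and senescence and p53 targets 0.07 (adjusted p = 0.558 for both). The medians were 0.07 for the piRNA pathway and germ granules (adjusted p = 0.600), 0.01 for the retinoic acid pathway (adjusted p = 0.459) and −0.04 for antioxidant defence (adjusted p = 0.426), and −0.06 for cell junctions and integrins (adjusted p = 0.409) and −0.06 for immediate-early genes (adjusted p = 0.196). The test, which sets a list against the other genes, ran lower while the median was above 0 for lymphocytes, the retinoic acid pathway, senescence, piRNA, Leydig and Sertoli lists, and the heat shock list had a mean of −0.02. With scaling to spike-in RNA the median of each of these uncalled lists was below 0, as was that of all genes (−0.35).

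Of the 32 lists, 15 were called, 6 higher and 9 lower, by camera with a preset correlation. With an estimated correlation 0 lists were called, fry called 1, and the exact permutation test of list means reached its smallest p, 0.0286, in 5 lists with 0 called after adjustment (smallest adjusted p = 0.183). Without young replicate 1 camera called 14 lists, 7 higher and 7 lower, 13 of them shared, and 0 with an estimated correlation (smallest adjusted p = 0.456).

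On the first principal component of all genes, which held 69.9% of the variance, young replicate 1 lay at −20.2 among the aged arrays (−50.8 to −10.0), and the other young arrays lay at 27.1 to 45.1. Across genes, which are not independent replicates, its values correlated at r = 0.985 to 0.989 with the aged arrays and at r = 0.962 to 0.973 with the other young arrays.

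**Figure D4:**
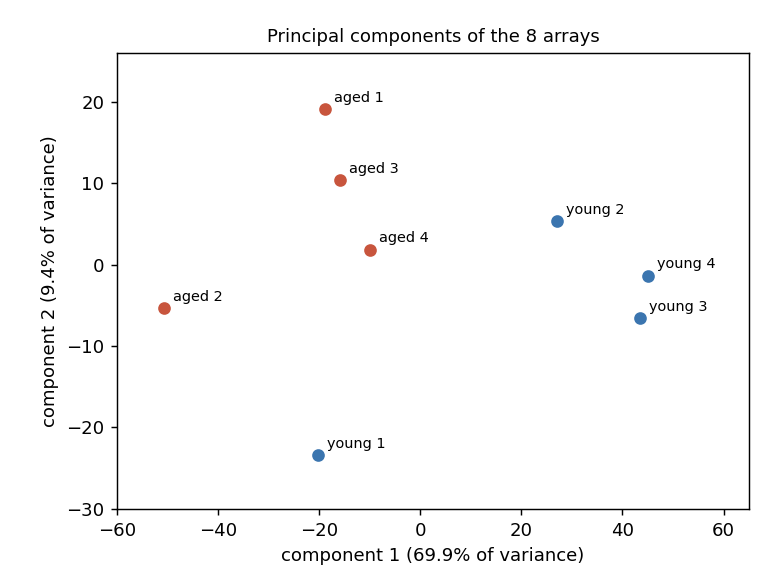
First and second principal components of the scaled log2 values of all tested genes, 1 point per array, with young arrays in blue and aged arrays in red; the axes hold 69.9% and 9.40% of the variance. Young replicate 1 lies at −20.2 on the first component with the aged arrays, and young replicates 2 to 4 lie at 27.1 to 45.1.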

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

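The tests of a wrong label, of less RNA of other cell types, of one shared lower share of other cells, of scaling as the source of either marker pattern, of dilution and of spermatocyte stage were chosen only after the results they bear on were seen. In 12 of 198 groups of 4 arrays 1 array lay far from the others, where chance gives about 1 in 20, and 8 of the 12 were set apart by young replicate 1. The gap of that array to its nearest neighbour, as a share of the group's range, was 0.881 for Adgre1, 0.849 for Col3a1, 0.856 for Col4a1 and 0.935 for Tex101, for each of which young replicate 1 was lowest. It was also lowest for the mean of the myoid and stromal list (0.901), the endothelial list (0.902) and the basement membrane and matrix list (0.857), and highest for Zbtb16 (0.887). Among aged arrays, replicate 2 was highest for Apom (0.855) and for the base excision repair list mean (0.885), replicate 3 for Atraid (0.926) and replicate 4 for Gpr4 (0.879).

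Of the 35 splits of the 8 arrays into 4 and 4, 2 gave at least 67 changed genes, the real one included, and the highest other gave 767. For genes higher in aged 2 splits gave at least 51 (highest other 671), for genes lower 2 gave at least 16 (highest other 96), and for lists 2 gave at least 15 (highest other 15). Chance could therefore not be excluded for any of these counts. The split with 767 genes set young replicate 1 and aged replicates 1 to 3 against the other arrays, aged replicate 4 included. The other splits that set young replicate 1 with 3 aged arrays gave 0 genes each. A split other than age can thus give more genes than the real one, but these counts alone cannot place young replicate 1 with the aged arrays.

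Young replicate 1 lay with the aged arrays on the first component, and 3 sources were weighed. Scaling was argued against for the settings tried, since its position (0, mean of aged, and 1, mean of the other young arrays) was at most 0.0759 under 5 other scalings. Median scaling shifts an array by 1 constant, and the authors' values repeated the main position (0.0595, against 0.0594). The argument therefore rests on the quantile and normexp settings (0.0422 to 0.0455). Spike-in scaling and no scaling were not among the 5. The spike-in level of young replicate 1 (1.79) lay among the aged arrays (1.64 to 2.06) and above the other young arrays (1.07 to 1.35). Less RNA of other testis cell types may account for the position, as 7 of 8 lists of such cells were lower in this array than in each other young array, with differences from −0.45 to −1.95 (log2), the lymphocyte list excepted. A wrong label stayed open, because the array lay nearer the aged mean at 79.7% of genes separating the other arrays, against 80.2% to 96.8% (SD 8.09) for aged arrays held out in turn. Its spermatocyte list mean of −0.22 was below that of every aged array (0.07 to 0.44) but inside their 95% prediction interval (−0.36 to 0.81). The other young arrays (−0.26 to −0.19) lay inside this interval too, so it cannot tell a wrong label from a right one. The undifferentiated spermatogonia mean of young replicate 1 (0.25) lay above the aged arrays (−0.12 to −0.03, SD 0.04). Its ribosomal mean did so too (0.25, against 0.10 to 0.13, SD 0.02). Its spermatid and stromal means (−0.58 and −0.76) lay inside the aged ranges. These further lists were picked after their values were seen. A wrong label could therefore be neither excluded nor preferred, and no biological explanation was tested.

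Spermatid, stromal and macrophage markers had lower values in aged samples. Scaling was argued against, since each of the 3 lists kept its call under 7 scalings, with a median nearest to 0 of −0.36. Median, spike-in and no scaling shift each array by 1 constant, and the authors' values nearly repeated the main medians. Such a shift moves all genes alike, so these calls were nearly fixed beforehand. The argument rests on the medians and on the quantile and normexp settings. One lower share of all other cells stayed open. Stromal markers fell more than Sertoli and Leydig markers (difference −1.35, exact permutation p = 0.0286, unadjusted). Young replicate 1 likewise lay further below the other young arrays for stromal markers (−1.95) than for Sertoli (−0.64) and Leydig markers (−0.57). An unequal fall thus also arose within 1 age and cannot decide the question. For spermatid (exact permutation p = 0.0571) and macrophage markers (exact permutation p = 0.114) aged replicate 4 (−0.085 and 0.46) overlapped the young arrays (lowest −0.14 and −0.038). Slide row, which cannot be told apart from age although the spermatid mean ranged over 1.66 (log2) within the young row alone, and a difference between the ages in the cells that pass the CD9 gate may each account for the pattern.

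The spermatocyte list was called higher in aged samples, although 5 of its 24 members had lower values. Dilution of germ cell RNA by other cells in the young arrays stayed open. The spermatocyte list rose relative to the undifferentiated spermatogonia list, from −0.29 ± 0.12 to 0.29 ± 0.15 (SD, n = 4, exact permutation p = 0.0286). Each list mean already separated the groups, in opposite directions (exact permutation p = 0.0286 for both), which fixed this p beforehand. The reference list also holds genes present on other cell types, such as Cd9, so the contrast could not decide on dilution. Scaling was argued against, as the list stayed called and its median stayed at 0.19 or more under 7 scalings. The calls carry the same limit for scalings that shift all genes alike. Whether more spermatocytes of all stages were sorted stayed open. The members lower in aged cells (median −0.94) did not rise with the others, but spermatid markers were lower too. Whether spermatids express these members was not measured here. Dilution in the young arrays, more early spermatocytes in the aged gate, higher transcript levels per cell with age, and slide row may each account for the rise. These were not separated by any test.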

How the results depend on the processing

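Scaling to spike-in RNA, the spermatid covariate, leaving out young replicate 1 and aged replicate 2 together, and testing unnamed probes were chosen after the data were seen. In all 25 alternatives that refit the genes, the called genes that were tested kept their direction (67 of 67, and 58 of 58 with the filter on all 8 arrays). The number passing, 67 with 51 higher and 16 lower, moved widely. The groups of each called gene were separated, so leaving out or weighting arrays could not turn a direction. Nor could the spike-in shift of 0.45, since the smallest called change was 0.56. Only settings that alter genes unequally, such as quantile scaling, normexp and the spermatid covariate, could have done so. The adjusted p-values of the 67 lay between 0.0314 and 0.0484. The counts stayed within 1.5 times with the authors' values (71), outlier spots kept (72), the filter on all 8 arrays (73) and the mean of a gene's probes (53). Quantile scaling gave 63 genes with 53 higher and 10 lower. Genes changed, higher and lower were 1330, 1067 and 263 with median scaling, 253, 219 and 34 with normexp and quantile scaling, and 630, 363 and 267 with normexp and percentile scaling. They were 270, 206 and 64 with a trended robust variance, 4564, 2884 and 1680 with array weights, 1059, 6 and 1053 with spike-in scaling, and 2804, 1386 and 1418 without young replicate 1 and aged replicate 2. They were 0, 0 and 0 in limma with no scaling (1389 genes at an unadjusted p under 0.05), with no filter on dim probes (3339), with the spermatid covariate (1294) and with unnamed probes tested too (4929 of 17596 probes and genes). At an adjusted p under 0.1 they were 1674, 946 and 728, at 0.01 they were 0, 0 and 0, and at an unadjusted p under 0.05 with at least 1.5-fold they were 1246, 257 and 989. Leaving out each array in turn gave 0 to 3776 changed genes, 0 to 2282 higher and 0 to 1494 lower, with 3776 without young replicate 1, 1 without young replicate 2 (2489 at an unadjusted p under 0.05) and 0 without any of the other 6 (1951 to 3009), and it gave 13 to 15 lists. The cause of these moves was not tested, except that a setting with fewer arrays or more genes tested changes the count by construction. Spike-in scaling also lowers all genes alike by construction.

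Same-numbered arrays did not deviate together (r = −0.26, −0.12, 0.44 and 0.35 across genes for numbers 1 to 4, and the arrays did not each correlate best with their own number), so the replicate number is not taken to pair them. With the number as a replicate block 0 genes were called, 0 higher and 0 lower (limma, 3231 at an unadjusted p under 0.05), and 15 lists.

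The 15 called lists became 9 with quantile scaling, 8 with normexp and quantile scaling, 12 with median scaling, with normexp and percentile scaling, with spike-in scaling and without both arrays, 14 with no scaling and with array weights, 5 with the spermatid covariate, 0 with an estimated correlation and 1 with fry. The spermatocyte list was called in 26 of 27 alternatives and lost only with the estimated correlation. The spermatid, stromal, macrophage and matrix lists were each called in 24 of 27. Undifferentiated spermatogonia and GDNF, FGF and KIT signalling were called in 16 of 27 each. Without young replicate 1 both of these were lost and cell cycle was gained (adjusted p = 0.0330, and adjusted p = 0.456 with an estimated correlation). Without young replicate 2 the cytokine and GDNF lists were lost, without aged replicate 2 the undifferentiated and nucleotide excision repair lists, without aged replicate 3 the undifferentiated list and without aged replicate 4 the GDNF list. With no filter on dim probes 15 lists were called, the undifferentiated list lost and the endothelial list gained.

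None of the 29 named called genes turned direction, which for separated groups many of the settings could not have caused. Of the 31 others, with spike-in scaling Atp5pb went to −0.034, Gtf2h5 to −0.11, Kit to −0.33, Rfc3 to −0.087, Rfc4 to −0.054, Rpl15 to −0.0044 and Rps19 to −0.025. With the spermatid covariate Id4 went to 0.0054 and Kit to −0.17. Zbtb16 went to 0.039 with quantile scaling, 0.061 with median scaling, 0.080 with array weights and 0.15 without both arrays, and ranged from −0.17 to 0.078 when each array was left out in turn. For lists the turn is that of the test, with the median given. With the spermatid covariate medians were 0.085 for spermatids, by construction, 0.070 for cytokines, 0.25 for Leydig cells and 0.25 for Sertoli cells (both called), 0.036 for antioxidant defence, −0.038 for apoptosis, −0.049 for cell cycle, 0.0082 for erythroid cells and 0.038 for the retinoic acid pathway. With quantile scaling they were 0.041 for ribosomal proteins, 0.017 for heat shock and 0.12 for lymphocytes, and heat shock had 0.013 with normexp and quantile scaling. Leydig cells had −0.40 and Sertoli cells −0.40 with spike-in scaling. Under fry the direction turned for Leydig cells (0.054), Sertoli cells (0.055), antioxidant defence (−0.044), piRNA (0.067) and senescence (0.074). Differentiating spermatogonia (0.049) and Sertoli cells (0.061) turned with the filter on all 8 arrays. Sertoli cells also turned with no scaling (0.024), without both arrays (0.16) and with unnamed probes (0.055). When each array was left out in turn the medians ran from −0.14 to 0.45 for Sertoli cells and from −0.12 to 0.11 for Leydig cells. The spike-in values of genes follow by construction from the shared shift of 0.45. The cause of the other turns was not tested.

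Signal over background limits the dim genes, since 13 of the 60 named genes, such as Akap14, Rhcg and Adh4, give no value when a probe must be above background on all 8 arrays.

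Other values too were more than 1.5 times smaller with normexp correction and quantile or percentile scaling. With quantile scaling after normexp Brca2 was 0.50, Rfc3 0.14, Rfc4 0.24, Gtf2h5 0.17, Atp5pb 0.18 and Rps19 0.20. With percentile scaling after it these were 0.61, 0.27, 0.35, 0.29, 0.37 and 0.39, within 1.5 times of the main values. Their smaller size therefore cannot be put down to normexp alone. With quantile scaling and no normexp Atp5pb was 0.23 and Brca2 0.69. Rpl15, Cd9 and Zbtb16 were 0.25, −0.027 and −0.0099 with quantile scaling after normexp, and 0.22, −0.086 and −0.048 with percentile scaling. Tg was 0.85 and the double-strand break repair list median 0.17 with percentile scaling after normexp. With quantile or percentile scaling after normexp list medians were −0.36 or −0.39 for macrophages, −0.090 or −0.097 for interferon response, −0.030 or −0.061 for cytokines, −0.057 or −0.051 for undifferentiated spermatogonia and −0.0063 or −0.012 for GDNF, FGF and KIT signalling. With quantile scaling after normexp they were 0.051 for ribosomal proteins, 0.097 for oxidative phosphorylation and 0.11 for nucleotide excision repair. With percentile scaling after normexp these were 0.23, 0.22 and 0.19, within 1.5 times of the main values. Quantile scaling without normexp gave 0.041 for ribosomal proteins.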

Other observations

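Several genes outside the fixed lists changed with age, chosen here after their values were seen. C14h1orf146, the rat counterpart of a human open reading frame gene known for meiotic recombination, rose by 0.72 ± 0.12 (log2, SE, limma adjusted p = 0.0465), and Hus1b, a paralogue of a checkpoint clamp subunit, rose by 0.69 ± 0.11 (adjusted p = 0.0465). Chgb and Scg5, proteins of secretory granules in endocrine cells, rose by 0.85 ± 0.12 and 0.83 ± 0.12 (adjusted p = 0.0465 for both), as did the secreted prohormone Tg. Falls outside the largest 12 included the complement inhibitor Serping1, which fell by 0.66 ± 0.11, and the signalling ligand Wnt7a, which fell by 0.90 ± 0.14 (adjusted p = 0.0465 for both). All of these held the same direction without young replicate 1, where their adjusted p ran from 0.00344 to 0.00583 apart from Tg (0.00301). Their groups were separated, so leaving out an array could not turn the direction. Leaving out any other single array left at most 1 called gene among all genes tested.

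The ribosomal protein list was nearly level across the aged arrays and spread across the young arrays, with an SD of its mean of 0.25 in the young group against 0.02 in the aged group (log2, n = 4). Young replicate 1 was at 0.25 and the other young arrays were at −0.30, −0.27 and −0.16. This difference in spread was not tested.

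A hypothesis that the rise within the spermatocyte list reaches meiotic genes outside the fixed lists was tested on a further list of 34 meiotic genes, written before its values were seen but after the spermatocyte result. Of these, 15 were measured and in no fixed list, 13 with higher and 2 with lower values in aged cells (Trip13 and Sun1), and the median change was 0.30. The list mean moved from −0.11 ± 0.10 to 0.11 ± 0.10 (SD, n = 4), with an exact permutation p of 0.0571, and camera gave p = 0.0920 with the preset and p = 0.327 with an estimated correlation. The largest values were in the synaptonemal complex gene Tex12 (0.62, adjusted p = 0.0561) and in Fignl1 (0.58, adjusted p = 0.0926). No member was called in limma over all genes (0 of 15), and 5 were called without young replicate 1. A wider rise of meiotic genes therefore did not pass the test.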
